A study of Mus musculus with 6 samples.

How the data were processed

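Gene expression was measured in C2C12 myotubes, which are multinucleated muscle cells formed by fusion of a mouse myoblast line when serum is lowered. Per the labels' protocols, cells were grown in 10% serum, differentiated in 2% serum, transfected with siRNA at 10 nM and given 200 µM oleate or palmitate bound to albumin (BSA), at 2.5 fatty acid molecules per BSA, or BSA alone, for 20 h. The siRNA was either a scrambled control or directed against Plin2. Total RNA with an integrity number above 8 was labelled with biotin from 100 ng and hybridised to Affymetrix whole-transcript arrays, 1 array for each of the 6 conditions.

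The deposited values are log2 expression values, 1 per probe set, and per the submitters' processing notes they were made by RMA, which corrects background, normalizes between arrays and summarises the probes of each probe set. The RMA version and a genome build are not given in the sources used here, so no coordinates are printed. The log base was read from the use of RMA and from the range of the values. The values were used as deposited, with no further scaling and no filter on low signal. Array medians over all 35556 probe sets lay between 4.94 and 5.02.

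Probe sets were named through the platform annotation of GEO. It tied 21789 probe sets to 1 gene symbol and 1621 to several, and it did not list 12146, which are unnamed here. The named probe sets stand for 19938 genes, 999 of them with more than 1 probe set; such a gene is given by its probe set with the highest mean. By Entrez ID, 21698 of the 21789 were matched to a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed.

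The layout crosses 2 siRNAs with 3 treatments and has no replicate of any condition. Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit with treatment and siRNA as terms, then eBayes with an intensity trend). The fit leaves 2 residual degrees of freedom, plus 9.21 borrowed from the spread across probe sets. The error of an siRNA change is therefore its variation between the 3 treatments, and the error of a fatty acid change is its variation between the 2 siRNAs. Nothing in the labels says whether the 6 cultures were separate or shared a day, so p-values measure only the spread between these arrays. An interaction model added a term for siRNA by any fatty acid and left 1 residual degree of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 21789 named probe sets, with a threshold of 0.05; every adjusted p for a gene comes from this limma test. Changes are log2 differences, given with a standard error (SE) or a 95% confidence interval. Bootstrap intervals of a list median resample the genes of the list 10000 times. They measure the spread between genes, which are not independent, and not the spread between arrays or cultures. The difference of the response to 1 fatty acid between siRNAs rests on 1 array per condition and has no test.

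Before the data were examined, 26 gene lists were written from textbook knowledge, along with the rule for naming genes and the alternatives. The lists were PPAR-responsive fatty acid genes, lipid droplet and triglyceride turnover, mitochondrial fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle, mitochondrial biogenesis regulators, cholesterol synthesis, fatty acid synthesis and desaturation, and LXR targets. They also covered ER chaperones, ATF4 and CHOP targets, NF-kB and inflammatory cytokines, interferon-stimulated genes, the NRF2 oxidative stress response, p53 targets, autophagy and lysosome, insulin signalling and glucose uptake, glycolysis, sphingolipids, and diacylglycerol with protein kinase C. Cell identity lists were contractile and differentiation genes, cell cycle genes, undifferentiated myoblast markers, fibroblast and matrix markers, adipocyte markers and osteoblast markers. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a contrast, then with an estimated correlation and with fry. With an estimated correlation the test has only the residual degrees of freedom of the fit, 2, or 1 for the interaction. It could hardly pass any list. A lost call there leaves the list undecided, and neither shows nor excludes that correlation between genes explains it. The sphingolipid list with oleate had an estimated correlation of -0.04, and its unadjusted camera p still went from 1.0e-06 to 0.032. Other lists were far above the preset, with estimates of 0.34 for oxidative phosphorylation, 0.35 for cholesterol synthesis and 0.54 for contractile genes. If those estimates hold, the preset test treats related genes as nearly independent, and its p-values for these lists are too small. Plin2 was left out of the list tests in the siRNA and interaction contrasts. A list's median and its camera test had opposite signs in 1 list of the siRNA contrast, 4 of oleate, 4 of palmitate and 1 of palmitate against oleate, none of them past the threshold.

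Named genes were Plin2 and up to 10 per direction with the largest change past the threshold and the same sign in every matched pair. Where fewer than 5 passed in a direction, the 5 with the largest change of that sign, among genes with a mean above the median, are given as values. Up to 4 members of each list with the smallest p were also named, and for the untested differences of response the 5 largest per direction among genes with a mean above the median. Other list members that are named passed the threshold and were picked after their values were seen.

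The alternatives were eBayes without the trend or with robust variance, removal of the lowest 33.3% of probe sets by mean, a repeat quantile normalization, centring on array medians, all 35556 probe sets, each array left out, fits on part of the arrays, and a paired test per gene without moderation. The median change with Plin2 siRNA over named probe sets was 0.01 as deposited and -0.01 after either scaling. The fits were tested on simulated data for 21789 probe sets with 200 changed. A change of 1 log2 unit was called in 98% of cases for siRNA, 95% for oleate and 96% for palmitate against oleate; a change of 0.5 was called in 44%, 22% and 21%, with 6, 10 and 1 false calls. With nothing changed there were 0 calls. The interaction model called 100% of changes of 2 log2 units and 69% of those of 1, with 37 false calls, more than in the other fits. The simulated change was the same for both fatty acids, so these shares do not hold for a response altered with only 1 of them. In the list simulation, the 1 shifted list was called, and so was 1 unshifted list of the 26 simulated. Its genes were drawn independently of each other, so it does not show how camera behaves on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.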

Results

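Messenger RNA was profiled in mouse C2C12 myotubes to ask how knockdown of perilipin 2 changes gene expression and the response to fatty acids. Perilipin 2 (Plin2) is a protein that coats lipid droplets. Of the 6 arrays, 3 were from cells with scrambled siRNA and 3 from cells with Plin2 siRNA, each with 1 array for BSA, oleate and palmitate. Oleate is a monounsaturated fatty acid and palmitate a saturated one with a shorter chain. The number of arrays limits the precision of every value. Correlations between arrays, across probe sets, were 0.995 to 0.997 within an siRNA and 0.989 to 0.993 between siRNAs. The first principal component held 57.1% of the variance and separated the siRNAs; the second held 16.6% and set scrambled palmitate (score -18.4) furthest from scrambled oleate (17.7).

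Plin2 itself was lower in every array of its siRNA. With scrambled siRNA its log2 expression was 9.29 in BSA, 10.03 in oleate and 10.10 in palmitate, and with Plin2 siRNA it was 6.95, 7.63 and 7.45. The knockdown lowered Plin2 by a log2 change of -2.47 (SE 0.08, n = 3 pairs of arrays, limma adjusted p = 2.3e-08), with pair values of -2.35, -2.40 and -2.65.

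**Figure D1:**
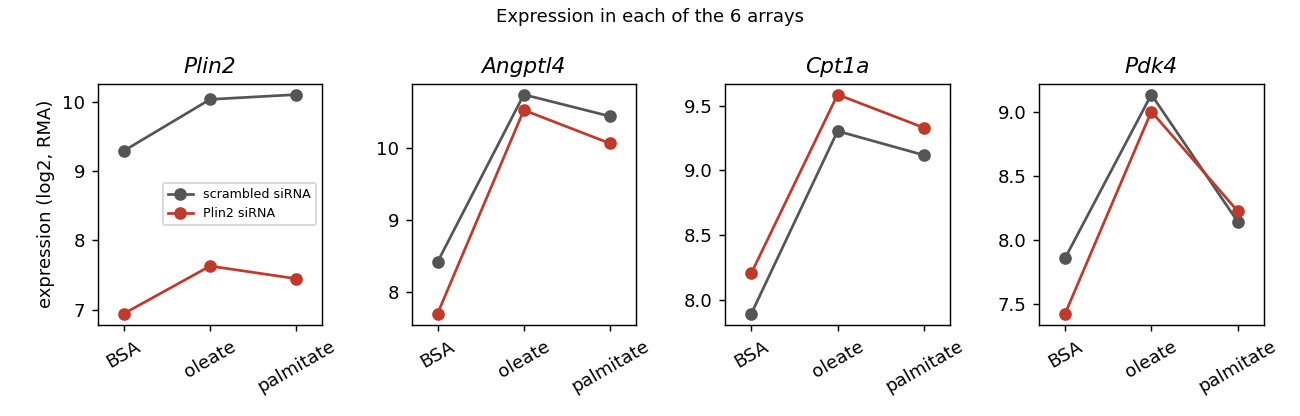
Log2 expression (vertical axis) of Plin2, Angptl4, Cpt1a and Pdk4 in BSA, oleate and palmitate (horizontal axis); each point is 1 array and lines join arrays of one siRNA. Plin2 lies between 6.95 and 7.63 with its siRNA and between 9.29 and 10.10 with scrambled siRNA, and Angptl4 is above its BSA value in all 4 fatty acid arrays.

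Knockdown of Plin2 was accompanied by a broad change in expression. More genes of oxidative metabolism rose than fell, and more genes of glycolysis, the amino acid stress response, lipid synthesis and the cell cycle fell than rose. Many members of these lists did not pass the threshold, and no list call held with an estimated correlation (lowest adjusted p = 0.51). That test had 2 degrees of freedom and could hardly pass any list. Among single genes, the muscle carbonic anhydrase Car3 rose most (3.53, SE 0.08, adjusted p = 1.7e-09), and the fatty acid transporter Cd36 rose by 2.21 (SE 0.23, adjusted p = 5.5e-05). The adhesion receptor Adgrg1 fell most (-3.10, SE 0.10, adjusted p = 2.3e-08), followed by the slow-muscle myosin light chain Myl2 (-3.05, SE 0.14, adjusted p = 2.1e-07). In all, 1851 probe sets rose and 1870 fell (3721 of 21789, for 1702 and 1774 genes), and 96 rose and 136 fell by at least 1 log2 unit.

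The other genes with the largest rises were Gbp8 (3.06), Serpinb6b (2.62), the Z-disc gene Myot (2.47), Nrn1 (2.44), the prostaglandin-degrading enzyme Hpgd (2.37), Igfbp3, which binds insulin-like growth factors (2.36), the myosin-binding protein Mybpc1 (2.35) and the carbonic anhydrase Car2 (2.14). Those with the largest falls were Prss46 (-2.74), the prostacyclin synthase Ptgis (-2.70), the calcium-storing protein Casq1 (-2.69), Sbk2 (-2.57), the dipeptidase Dpep1 (-2.47), Tppp3 (-2.40) and the interferon-induced gene Ifit1 (-2.14). Each of these changed in the same direction in all 3 pairs of arrays.

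**Figure D2:**
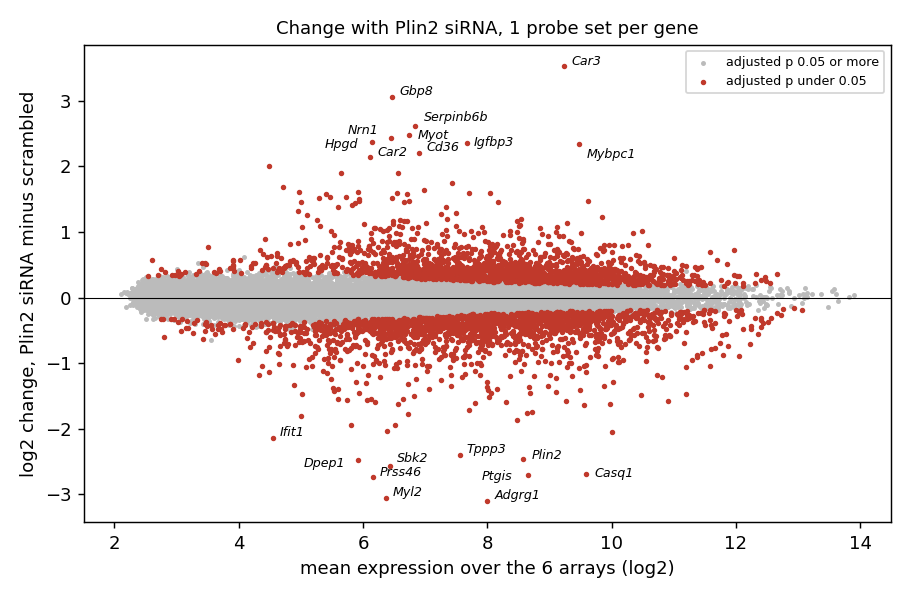
Log2 change with Plin2 siRNA against scrambled siRNA (vertical axis) by mean log2 expression over the 6 arrays (horizontal axis), 1 point per gene and red where the adjusted p was under 0.05. Car3 stands at 3.53, and 7 genes, Adgrg1 to Dpep1, lie below Plin2 at -2.47.

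Of the 26 lists, 13 passed camera in this contrast and 0 passed with an estimated correlation. Some mitochondrial genes rose, though most members of the mitochondrial lists did not pass the threshold. In mitochondrial fatty acid oxidation, 10 of 24 measured members rose and 0 fell (11 and 0 adjusted over the list alone). The carnitine carrier Slc25a20 (0.56), the dehydrogenases Acadl (0.50) and Hadh (0.49), and the isomerase Eci2 (0.44), were among them. The list passed camera (median 0.18, adjusted p = 1.9e-05), but not with an estimated correlation (adjusted p = 0.51). Its median was 0.08 in BSA, 0.18 in oleate and 0.28 in palmitate. In oxidative phosphorylation, 21 of 55 rose and 0 fell (26 and 0 adjusted over the list alone), including Ndufa3 (0.67), Atp5g3 (0.57) and Ndufs3 (0.48). Its median was 0.19 (camera adjusted p = 1.3e-11, and adjusted p = 0.51 with an estimated correlation), made of 0.12 in BSA, 0.18 in oleate and 0.27 in palmitate. In the tricarboxylic acid cycle, 7 of 21 rose and 0 fell (7 and 0 adjusted over the list alone), including Idh3a (0.32) and Sdhd (0.28). The median was 0.10 (camera adjusted p = 0.0045, and adjusted p = 0.56 with an estimated correlation). It was made of 0.03 in BSA, where 11 members lay above 0 and 10 below, 0.08 in oleate and 0.23 in palmitate. Of the mitochondrial biogenesis regulators, 3 of 25 rose and 0 fell (6 and 0 adjusted over the list alone). They were the coactivator Ppargc1a (1.52), the AMP-activated kinase subunit Prkaa2 (1.08) and the receptor Ppara (0.54); the list did not pass camera (adjusted p = 0.16) and passed fry (adjusted p = 0.047).

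Several glycolysis genes fell, and insulin signalling genes went both ways. Of 17 measured glycolysis genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone): among them were Pfkp (-1.74), the lactate transporter Slc16a3 (-1.42), the glucose transporter Slc2a1 (-1.35) and hexokinase Hk2 (-1.19). The median was -0.23 (adjusted p = 6.9e-08), with adjusted p = 0.51 with an estimated correlation and 0.047 by fry. In insulin signalling and glucose uptake, 5 of 31 rose and 7 fell (6 and 8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.23). The Rab regulator Tbc1d1 (-1.20) and Pik3cb (-0.99) fell. Of members picked after their values were seen, the insulin-regulated transporter Slc2a4 (-0.86) and the insulin receptor Insr (-0.34) fell, while Igf1r (0.53) and the receptor substrate Irs1 (0.52) rose.

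Lipid genes went in several directions. Of the PPAR-responsive fatty acid genes, 8 of 34 rose and 3 fell (8 and 3 adjusted over the list alone), without a call for the list (adjusted p = 0.15): besides Cd36, Lpl (0.86) rose, and the hormone Fgf21 (-2.05) and the binding protein Fabp3 (-1.45) fell. Of lipid droplet and triglyceride genes other than Plin2, 1 of 29 rose, Fitm1 (1.60), and 4 fell, among them Gpat3 (-1.12) and Agpat2 (-0.55), with 1 and 5 adjusted over the list alone (list adjusted p = 0.29). In cholesterol synthesis, 9 of 21 fell and 1 rose (11 and 1 adjusted over the list alone). Sqle (-0.52), Ebp (-0.42) and Cyp51 (-0.41) fell, and the gene that rose was Srebf2, the regulator of the pathway (0.20). The median was -0.23 (camera adjusted p = 3.7e-05, and adjusted p = 0.51 with an estimated correlation), made of -0.46 in BSA, -0.21 in oleate and -0.13 in palmitate. In fatty acid synthesis and desaturation, 8 of 20 fell and 0 rose (10 and 0 adjusted over the list alone), including the desaturase Fads2 (-0.83) and the elongase Elovl5 (-0.73); the median was -0.21 (adjusted p = 4.4e-05, and adjusted p = 0.51 with an estimated correlation).

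In the stress-response lists that follow, more members fell than rose. Of 36 ATF4 and CHOP targets, which respond to amino acid shortage and ER stress, 21 fell and 0 rose (24 and 0 adjusted over the list alone), including Mthfd2 (-1.07), Nupr1 (-0.84) and the amino acid transporter Slc7a1 (-0.79). The median was -0.36 (adjusted p = 1.2e-13, and adjusted p = 0.51 with an estimated correlation). Of 25 ER chaperone genes, 8 fell and 0 rose (12 and 0 adjusted over the list alone), including Ostc (-0.78) and Dnajc3 (-0.66); the median was -0.16 (adjusted p = 4.4e-06, and adjusted p = 0.51 with an estimated correlation). Of 23 p53 targets, 10 fell and 3 rose (11 and 3 adjusted over the list alone), with Gadd45a at -1.04 and Trp53inp1 at 0.62; the median was -0.21 (adjusted p = 4.8e-05, and adjusted p = 0.51 with an estimated correlation). Of 37 interferon-stimulated genes, 5 fell and 1 rose (4 and 1 adjusted over the list alone): besides Ifit1, Cxcl10 fell (-1.04), and Trim25 rose (0.78). The median was -0.13 (camera adjusted p = 0.0093, and adjusted p = 0.51 with an estimated correlation), made of -0.08 in BSA, -0.08 in oleate and -0.26 in palmitate.

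Muscle identity genes moved in both directions. Of 50 contractile and differentiation genes, 20 fell and 6 rose (25 and 7 adjusted over the list alone); besides Casq1, Mybpc2 (-1.95) and the differentiation factor Myog (-0.69) fell; Mef2c (1.23), picked after its value was seen, rose with Mybpc1. The median was -0.18 (adjusted p = 3.2e-05, and adjusted p = 0.56 with an estimated correlation), made of -0.26 in BSA, -0.17 in oleate and -0.02 in palmitate. Of 35 cell cycle genes, 18 fell and 0 rose (19 and 0 adjusted over the list alone), including Mcm6 (-0.90) and Rrm2 (-0.82); the median was -0.29 (adjusted p = 2.0e-09, and adjusted p = 0.51 with an estimated correlation). Of 20 undifferentiated myoblast markers, 7 rose and 5 fell (9 and 7 adjusted over the list alone), with Id3 at 1.60 and Itga7 at -0.73, and the list did not pass camera (adjusted p = 0.30). Of 27 fibroblast and matrix markers, 10 fell and 3 rose (12 and 3 adjusted over the list alone), with Tnc at -1.40 and Timp1 at -0.96; the median was -0.10 (adjusted p = 0.0045, and adjusted p = 0.55 with an estimated correlation).

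**Figure D3:**
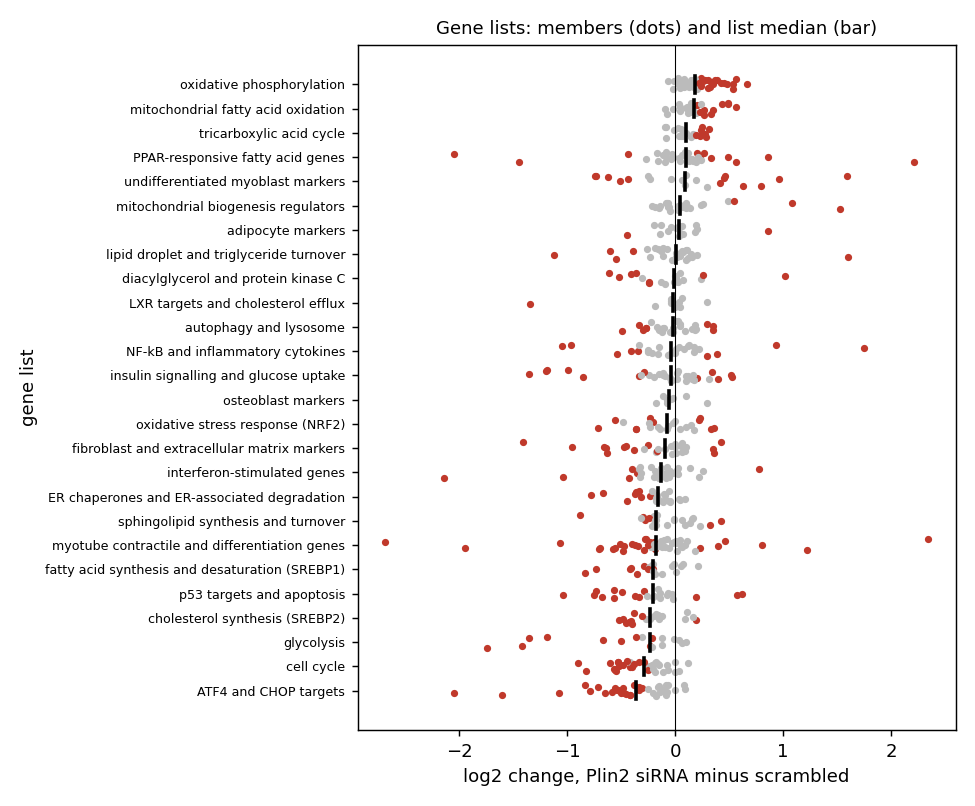
Log2 change with Plin2 siRNA (horizontal axis) of the members of each of the 26 gene lists (rows), Plin2 left out. Each dot is a gene, red where its adjusted p was under 0.05, the vertical place of a dot within a row has no meaning, and each black bar is the list median, which runs from -0.36 for ATF4 and CHOP targets to 0.19 for oxidative phosphorylation.

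The count of 3721 changed probe sets fell to 2403 without the intensity trend, 2159 with all probe sets in the fit, 2215 without the scrambled BSA array and 2213 without the Plin2 siRNA BSA array. The counts without a BSA array are in effect the same check, because an array whose partner is left out carries no information on the siRNA change. A paired test per gene without moderation called 0, and Plin2 then had an adjusted p of 0.17.

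Oleate raised a few genes of fatty acid use and lowered a few genes of sterol and fatty acid synthesis. Most members of these lists did not pass the threshold, and no list call held with an estimated correlation (lowest adjusted p = 0.53). The secreted lipase inhibitor Angptl4 rose by 2.57 (SE 0.11, n = 2 pairs of arrays, adjusted p = 1.2e-06), Pdk4, which restrains glucose oxidation, by 1.43 (SE 0.12, adjusted p = 0.00058), and Cpt1a by 1.40 (SE 0.08, adjusted p = 2.9e-05). Plin2 rose by 0.71 (SE 0.10, adjusted p = 0.023), from different baselines, by 0.74 with scrambled and 0.69 with Plin2 siRNA; this call was lost without the intensity trend (adjusted p = 0.58), with all probe sets (0.52), after quantile normalization (0.056) and without scrambled BSA (0.43). In all 7 probe sets rose and 9 fell; 1365 had an unadjusted p under 0.05, where chance gives 1089. The other rises were Rnf145 (0.80), Malat1 (0.61) and the metallothionein Mt2 (0.53). The falls were the gap junction gene Gja5 (-1.01), the sterol enzymes Nsdhl (-0.86), Tm7sf2 (-0.66), Cyp51 (-0.64), Fdps (-0.64) and Msmo1 (-0.58), the sterol-regulated gene Insig1 (-0.76), and the desaturases Fads2 (-0.81) and Scd2 (-0.68).

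Of the 26 lists, 11 passed camera with oleate and 0 with an estimated correlation. In the cholesterol synthesis list, 6 of 21 genes fell with oleate and 0 rose (17 and 0 adjusted over the list alone), and all 21 had a fitted change below 0. The median was -0.50 (adjusted p = 1.4e-33, and adjusted p = 0.53 with an estimated correlation). In fatty acid synthesis and desaturation, 2 of 20 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.21 (adjusted p = 4.0e-11, and adjusted p = 0.55 with an estimated correlation). Of 35 PPAR-responsive genes, 4 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.10 (adjusted p = 3.2e-11, and adjusted p = 0.56 with an estimated correlation). In mitochondrial fatty acid oxidation 1 of 24 rose, Cpt1a (7 adjusted over the list alone), and Acaa2 stood at 0.65 (adjusted p = 0.14) and Acadl at 0.42 (adjusted p = 0.15). The list median was 0.15 (adjusted p = 2.1e-13, and adjusted p = 0.56 with an estimated correlation).

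The oleate count of 16 was 0 with all probe sets in the fit, 2 without the intensity trend (2 up, 0 down) and 31 without the lowest 33.3% of probe sets by mean, and its split of 7 up and 9 down became 7 and 5 after centring. Leaving out 1 array gave 3 without scrambled BSA (3 up, 0 down), so each fall lost its call there too, 62 without scrambled oleate, 65 without scrambled palmitate, 262 without Plin2 siRNA oleate and 66 without Plin2 siRNA palmitate. The counts without a palmitate array are in effect the same fit, on the BSA and oleate arrays.

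Palmitate raised Angptl4 by 2.19 (SE 0.11, n = 2 pairs of arrays, adjusted p = 7.1e-06) and Cpt1a by 1.18 (SE 0.08, adjusted p = 0.00018). These were the 2 probe sets past the threshold, and 0 fell; 1134 had an unadjusted p under 0.05, where chance gives 1089. Plin2 stood at 0.66 (SE 0.10, adjusted p = 0.16), with 0.81 in scrambled and 0.50 in Plin2 siRNA cells. The fast myosin gene Myh4 stood at -0.92 (SE 0.13, adjusted p = 0.16). Below the threshold, the glutathione transferase Gsta4 stood at 0.78, Bdkrb1 at 0.64, Adm at 0.58, Dhrs3 at 0.56, Slc44a4 at -0.92, Grhl3 at -0.81, Hephl1 at -0.79 and Fsd2 at -0.74.

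Of the 26 lists, 13 passed camera with palmitate and 0 with an estimated correlation. Of the contractile genes, 0 of 50 passed the threshold (0 up and 13 down adjusted over the list alone); the list median was -0.15 (adjusted p = 3.1e-16, and adjusted p = 0.57 with an estimated correlation). That median was -0.24 in scrambled cells and -0.03 in Plin2 siRNA cells. Fibroblast and matrix markers, 0 of 27 past the threshold, had a median of 0.05, made of 0.12 in scrambled and -0.02 in Plin2 siRNA cells. Their list passed camera (adjusted p = 0.0036, and adjusted p = 0.59 with an estimated correlation). Myoblast markers, 0 of 20 past the threshold, had a median of -0.08 (camera adjusted p = 0.017, and adjusted p = 0.57 with an estimated correlation). Of 35 cell cycle genes, 0 passed (0 adjusted over the list alone), with a median of 0.15 (adjusted p = 1.6e-07, and adjusted p = 0.57 with an estimated correlation), made of 0.30 in scrambled and 0.04 in Plin2 siRNA cells. Oxidative phosphorylation had 0 of 55 members past the threshold (0 adjusted over the list alone) and a median of -0.11 (adjusted p = 2.0e-10, and adjusted p = 0.57 with an estimated correlation), made of -0.18 in scrambled and -0.04 in Plin2 siRNA cells. Of 21 cholesterol synthesis genes 0 passed (0 adjusted over the list alone), with a median of 0.14 (adjusted p = 6.0e-08, and adjusted p = 0.57 with an estimated correlation), made of 0.03 in scrambled and 0.24 in Plin2 siRNA cells. Of 25 ER chaperone genes 0 passed (0 adjusted over the list alone), with Hyou1 at 0.29 and a list median of 0.09 (adjusted p = 1.1e-06, and adjusted p = 0.57 with an estimated correlation).

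The palmitate count of 2 was 0 with all probe sets in the fit and 119 on the 4 BSA and palmitate arrays alone. It was 116 without scrambled oleate (34 up, 82 down), 117 without Plin2 siRNA oleate (36 up, 81 down) and 98 without Plin2 siRNA palmitate (21 up, 77 down), so falls outnumbered rises there. The counts of 116, 117 and 119 come in effect from the same fit, because an oleate array without its partner carries no information on the palmitate change.

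The fatty acids were then compared directly at the same dose and time; they differ in the cis double bond of oleate and in chain length. Of the cholesterol synthesis genes, 12 of 21 were higher with palmitate than with oleate, though the call of the list did not hold with an estimated correlation (adjusted p = 0.45). The desaturase Fads2 differed most (1.23, 95% interval 1.03 to 1.43, adjusted p = 0.00069), and Nsdhl differed by 1.15 (0.94 to 1.36, adjusted p = 0.00096) and Insig1 by 1.05 (0.84 to 1.27, adjusted p = 0.0013). Rnf145 was lower with palmitate by -1.13 (-1.35 to -0.91, adjusted p = 0.00096) and Pdk4 by -0.89 (-1.14 to -0.63, adjusted p = 0.011). No difference was called for Plin2 (-0.06, interval -0.27 to 0.16, adjusted p = 0.92), Angptl4 (-0.38, -0.62 to -0.15, adjusted p = 0.29) or Cpt1a (-0.22, -0.40 to -0.04, adjusted p = 0.46).

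In all, 31 probe sets were higher and 26 lower with palmitate, and 2007 had an unadjusted p under 0.05, where chance gives 1089. Also higher were Serpinb9e (1.16), Gja5 (1.15), Tm7sf2 (0.95), Lss (0.88), Hsd17b7 (0.85), Zfp459 (0.83) and Rrad (0.80). Also lower were Fsd2 (-1.17), the galactosyltransferase B4galt5 (-1.15), Cd28 (-1.14), Slc44a4 (-1.07), Mamdc2 (-1.03), Galnt5 (-0.92), Gramd1b (-0.88) and Mfsd7a (-0.88).

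Of the 26 lists, 14 passed camera in this contrast and 0 with an estimated correlation. Of 21 cholesterol synthesis genes, 12 were higher with palmitate and 0 lower (19 and 0 adjusted over the list alone). The median was 0.61 (adjusted p = 5.5e-39, and adjusted p = 0.45 with an estimated correlation), with 0.62 in scrambled and 0.65 in Plin2 siRNA cells. In fatty acid synthesis and desaturation, 4 of 20 were higher and 0 lower (9 and 0 adjusted over the list alone), adding Scd2 (0.74), Scd1 (0.50) and Mid1ip1 (0.46) to Fads2. The median was 0.21 (adjusted p = 7.9e-10, and adjusted p = 0.45 with an estimated correlation). In oxidative phosphorylation 1 of 55 was lower, Cox8b (-0.78), and 0 higher (4 and 0 adjusted over the list alone), with a median of -0.13 (adjusted p = 6.8e-13, and adjusted p = 0.48 with an estimated correlation). Of 50 contractile genes 1 was lower, Myh4 (-0.77), and 0 higher (8 and 1 adjusted over the list alone), with a median of -0.07 (adjusted p = 5.3e-05, and adjusted p = 0.58 with an estimated correlation). The contractile median was made of -0.15 in scrambled and 0.007 in Plin2 siRNA cells.

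**Figure D4:**
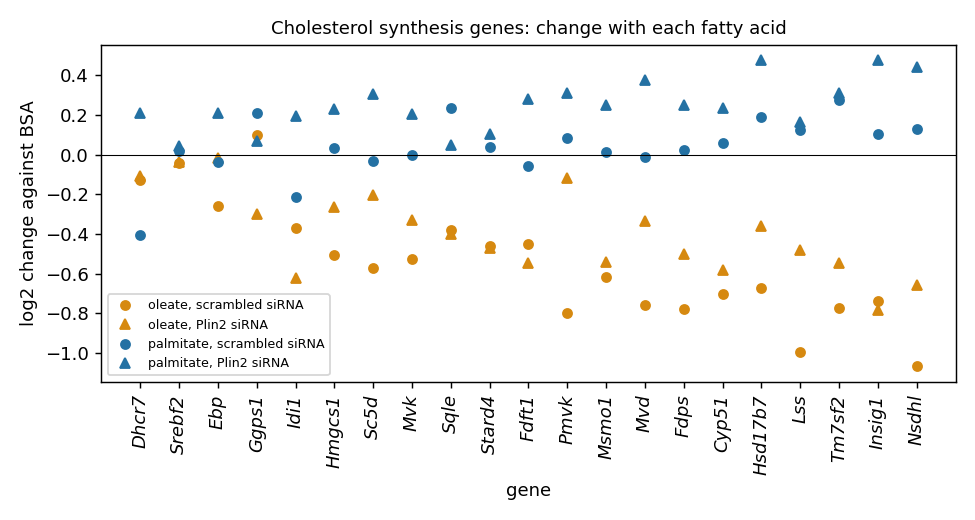
Log2 change against BSA (vertical axis) of the 21 measured cholesterol synthesis genes (horizontal axis) with oleate (orange) and palmitate (blue), in scrambled (circles) and Plin2 siRNA cells (triangles). Each point is a difference of 2 arrays; Nsdhl stands at -1.07 and -0.66 with oleate and at 0.13 and 0.44 with palmitate.

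The count of 57 was 0 without the intensity trend, 0 with all probe sets in the fit, 25 after a repeat quantile normalization and 86 on the 4 fatty acid arrays alone. Leaving out 1 array gave 112 without scrambled oleate, 30 without scrambled palmitate, 538 without Plin2 siRNA oleate and 440 without Plin2 siRNA palmitate.

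The responses to the 2 fatty acids shared Angptl4 and Cpt1a. Both genes that rose with palmitate were among the 7 that rose with oleate, where independent lists would share 0.00064. Across 21789 probe sets, which are not independent replicates, the fitted responses had r = 0.365 and a covariance of 0.0078. Unchanged groups simulated against the shared BSA arrays gave r = 0.501 and a covariance of 0.0082 (mean of 100 simulations). Between arrays that shared no BSA array, r was 0.101 (oleate in scrambled against palmitate in Plin2 siRNA cells) and -0.034 (the reverse). Angptl4 and Cpt1a rose with each fatty acid in each siRNA arm, as given below. This argues against shared controls as the source of their overlap. Across probe sets, the correlation was no higher than shared controls alone gave, so it is no evidence of a wider common response.

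The last comparison asked whether Plin2 knockdown changed the response to fatty acids. Angptl4 rose in both siRNA arms, by 2.32 and 2.82 with oleate and by 2.02 and 2.36 with palmitate (scrambled, then Plin2 siRNA). Cpt1a stood at 1.41 and 1.38 with oleate and at 1.23 and 1.13 with palmitate. The interaction model in limma called 0 probe sets, with 551 at an unadjusted p under 0.05 where chance gives 1089, and 0 in each alternative run. The error of this model is the part of the difference that varies between oleate and palmitate. A response altered with only 1 of them therefore adds to that error, and the 0 calls say little about it. Among the 26 lists, 10 passed camera and 0 passed with an estimated correlation, the lowest adjusted p being 0.91. With 1 residual degree of freedom, the test with an estimated correlation could hardly pass any list. The cholesterol synthesis list had a median of 0.20 toward higher values in Plin2 siRNA cells, and the NF-kB and cytokine list had a median of -0.24.

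For each fatty acid alone the difference has no replicate check. The oleate response differed by at least 1 log2 unit in 37 probe sets, 17 higher and 20 lower in Plin2 siRNA cells. Among genes with a mean above the median, of which 2 were higher and 2 lower by that much, Gadl1 (1.11), Snora44 (1.01), Dpep1 (0.94), Lrp8 (0.88) and Myl2 (0.82) were highest, and Gm10785 (-1.23), Ptma-ps2 (-1.04), Gm10767 (-0.91), the chemokine Cxcl5 (-0.83) and Gm10142 (-0.80) lowest. The palmitate response differed by that much in 79, 30 higher and 49 lower. A repeat quantile normalization turned that split to 36 and 24, and centring turned it to 40 and 21. Probe sets with a mean above the median split the other way, with 9 higher and 5 lower by at least 1 log2 unit. Among genes with a mean above the median, the palmitate response difference was highest for Cd24a (2.20), Cd36 (1.37), Mef2c (1.17), Asb16 (1.08) and Tspan13 (1.05), and lowest for Macrod2 (-1.41), Gsta4 (-1.24), Gm7102 (-1.06), Tesc (-1.05) and Gm10142 (-1.02). Cd36 was 6.07 in BSA and 4.82 in palmitate with scrambled siRNA, and 7.89 and 8.01 with Plin2 siRNA. Mef2c was 9.70 and 8.42 with scrambled siRNA, and 10.52 and 10.41 with Plin2 siRNA.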

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

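The list tests and the count of splits were planned, and the other tests of explanations in this part were chosen after the values they bear on had been seen; for both differentiation tests and the test on abundant transcripts, what would count against the explanation was also revised after the result. What drew attention was a difference between the siRNAs in the response to fatty acids, tested on each gene list in the interaction model. In Plin2 siRNA cells the response was higher for cholesterol synthesis (median difference 0.20), contractile genes (0.14), the tricarboxylic acid cycle (0.12), ATF4 and CHOP targets (0.12), PPAR-responsive genes (0.12), fatty acid oxidation (0.10), oxidative phosphorylation (0.077) and fatty acid synthesis (0.066). It was lower for NF-kB and cytokine genes (-0.24) and cell cycle genes (-0.20). Higher and lower refer to the signed change, so a higher value can be a smaller fall. From scrambled to Plin2 siRNA cells, the cholesterol synthesis median went from -0.57 to -0.40 with oleate and from 0.03 to 0.24 with palmitate. With palmitate, the contractile median went from -0.24 to -0.03 and the tricarboxylic acid cycle median from -0.20 to -0.04. The median differences pool the fatty acids, and several rest mostly on one of them. Random lists of matched expression could lie above 0 (middle 95% 0.023 to 0.118 for oxidative phosphorylation with palmitate). Cholesterol synthesis, NF-kB and cell cycle genes lay outside their range with both fatty acids. The others did so with only 1. Inside with palmitate were fatty acid synthesis (percentile 73.6) and ATF4 targets (56.5). Inside with oleate were fatty acid oxidation (33.6), oxidative phosphorylation (44.8), PPAR-responsive, contractile and tricarboxylic acid cycle genes. With oleate and then palmitate the median differences were 0.02 and 0.22 for fatty acid oxidation, 0.02 and 0.16 for oxidative phosphorylation, 0.06 and 0.22 for contractile genes, 0.08 and 0.20 for PPAR-responsive genes, and 0.23 and 0.07 for ATF4 and CHOP targets; whether the fatty acids differ in this was not tested. All 10 passed camera at the preset correlation, and with an estimated correlation, on 1 degree of freedom, each had an adjusted p of 0.91. No condition had enough arrays to look for single outlying samples.

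The first pattern weighed was the 3721 probe sets changed by Plin2 siRNA. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many, the real one. The highest of the others gave 0, but in those splits the difference between the siRNAs counts as error, which lowers their counts. Also, 10 splits are too few for a share under 0.05. Less differentiated Plin2 siRNA cultures stay open: contractile and differentiation genes were lower, which goes with it (median -0.18, 95% bootstrap interval -0.22 to -0.08, but -0.02 in the palmitate pair), and cell cycle genes were lower rather than higher, which goes against it (median -0.29, interval -0.44 to -0.19). Direct silencing of other genes by the oligo cannot be told apart from loss of Plin2: 7 genes fell further than Plin2, and the number of oligos and their sequences are not given in the sources used here. Rises were 99.0% of falls, but this balance moved with scaling (1777 and 1955 after quantile normalization, 1379 and 1817 after centring) and decides nothing; an effect of Plin2 loss itself also stays open, and the labels name no batch to test.

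The second was the lower expression of cholesterol synthesis genes with oleate than with palmitate. A single deviating array is argued against by both arms, which share no array. The list median was 0.62 in the lower arm (95% bootstrap interval over genes 0.50 to 0.80) and 0.65 in the other. A shift of whole arrays is argued against by 10000 random lists matched on mean expression, whose highest median was 0.14 against 0.61 for the list. A general fall of abundant transcripts with oleate is argued against by oxidative phosphorylation, with a median of -0.13 (interval -0.15 to -0.10); glycolysis had -0.04 (interval -0.07 to 0.04). As a hypothesis, oleate may lower this pathway where palmitate does not; handling shared by the oleate cultures was not tested.

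The last was the palmitate shift in scrambled cells, with contractile genes at -0.24 and cell cycle genes at 0.30 against BSA. Against oleate as the reference it was smaller, -0.15 and 0.14. Part of it may rest on the scrambled BSA array, or oleate may shift these genes in the same direction. Oleate against BSA in scrambled cells gave medians of -0.10 and 0.07, which cannot tell these apart. Whether the references differ was not tested. For the part that remained, a peculiarity of the scrambled palmitate array or its culture cannot be told apart from a palmitate effect that Plin2 knockdown removes. Fewer differentiated cells in that culture remain possible: myoblast markers were lower (median -0.11, 95% bootstrap interval -0.17 to -0.02), which goes against it, and the cell cycle shift of 0.30 goes with it. Fibroblast and matrix markers were also higher there (median 0.12, against -0.02 in Plin2 siRNA cells), which leaves a change in cell make-up open.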

How the results depend on the processing

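All alternatives were set before the data were examined. The direction of the Plin2 knockdown held in all of them, and only the paired test without moderation left it short of the threshold (-2.47, adjusted p = 0.17; the other adjusted p-values ran up to 0.0023). Probe sets changed by Plin2 siRNA numbered 3721, against 2403 without the intensity trend, 2159 with all probe sets, 2219 without both BSA arrays and 0 by the paired test. Leaving out 1 array gave 2213 (Plin2 siRNA BSA) to 3836, with 2215 without scrambled BSA. Leaving out 1 BSA array or both is in effect the same check. For oleate, 16 became 2 without the trend, 31 without the lowest 33.3%, 0 with all probe sets and 64 on 4 arrays; leaving out 1 array gave 3 to 262. For palmitate, 2 became 0 with all probe sets and 119 on 4 arrays, and 2 to 117 on leaving out 1. For palmitate against oleate, 57 became 0 without the trend, 0 with all probe sets, 25 after quantile normalization and 86 on 4 arrays, and 30 to 538 on leaving out 1. Each fit on 4 arrays is in effect the same as leaving out 1 array of the remaining treatment. The cause of these changes in count was not tested. Fits with arrays left out, which had 1 residual degree of freedom, borrowed from 11.16 to 690.47 degrees of freedom from other probe sets. The full fit borrowed 9.21. The interaction count was 0 in every alternative run. Differences of response of at least 1 log2 unit numbered 37 for oleate (20 without the lowest 33.3%, 1180 with all probe sets) and 79 for palmitate (40 and 1218). The correlation of the responses, 0.365, was 0.311 without the lowest 33.3%, 0.378 after quantile normalization, and 0.101 and, reversed, -0.034 on arrays not shared. For named genes, 2153 results kept their direction and side of the threshold, 40 passed newly, 327 no longer passed and 1 reversed: Plin2 in palmitate against oleate, 0.084 without the Plin2 siRNA palmitate array and -0.197 without the scrambled one. The Plin2 rise with oleate did not pass without the trend (adjusted p = 0.58), with all probe sets (0.52), after quantile normalization (0.056) or without scrambled BSA (0.43). For gene lists, 264 results stayed on their side of the threshold, 124 lost a call and 2 gained one, and no list call held with an estimated correlation. That test had 2 degrees of freedom, or 1 for the interaction. No paired analysis by replicate number was possible because each condition has 1 array; treatment is a block in the siRNA fit. No background or detection value was used here, so low signals could not be told from background.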

Other observations

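The list tests in this part were planned; the tests of fibre genes and of PPAR induction were chosen after part of the values they bear on had been seen, and what would count against a weaker PPAR induction was revised after the result. The separate fit of unnamed probe sets was not planned. Several gene groups had members that moved in both directions with Plin2 siRNA, with no camera call for the list. Of 28 NF-kB and cytokine genes, 4 rose and 5 fell (4 and 10 adjusted over the list alone; list adjusted p = 0.40). The pentraxin Ptx3 (1.75) and the chemokine Cxcl5 (0.94) rose, and Lcn2 (-1.05) and the prostaglandin synthase Ptgs2 (-0.96) fell. Of 23 NRF2 genes, 4 rose and 6 fell (4 and 9 adjusted over the list alone; list adjusted p = 0.18), with Fth1 at 0.36 and Abcc1 at -0.56. Of 27 autophagy and lysosome genes, 3 rose and 5 fell (6 and 6 adjusted over the list alone; list adjusted p = 0.45), with Map1lc3b at 0.35 and Hexa at -0.49.

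Of 24 sphingolipid genes, 2 rose and 4 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.15), with the ceramide kinase Cerk at -0.88 and the sphingosine kinase Sphk2 at 0.43. Of 19 diacylglycerol and protein kinase C genes, 2 rose and 6 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.15), with the diacylglycerol kinase Dgke at 1.02 and Plcb3 at -0.61. Of 10 LXR targets, 1 fell, Pltp (-1.35), and 0 rose (1 and 0 adjusted over the list alone; list adjusted p = 0.47). Of 16 adipocyte markers 1 rose, Lpl (0.86), and 1 fell, Lgals12 (-0.45), with 1 and 1 adjusted over the list alone (list adjusted p = 0.72). Of 8 osteoblast markers 0 passed the threshold (0 adjusted over the list alone; list adjusted p = 0.79).

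Contractile genes changed in opposite directions after Plin2 siRNA, and a shift from fast to slow fibre genes was tested as a hypothesis. Of 12 slow fibre genes 2 rose and 6 fell, and of 14 fast fibre genes 1 rose and 7 fell, with medians of -0.24 and -0.25. The medians differed by 0.0096 (permutation test over genes, 100000 resamples, two-sided p = 0.91), which leaves the hypothesis open. Among members picked after their values were seen, within the slow genes Mybpc1 rose by 2.35 while Myl2 (-3.05) and Myoz2 (-1.06) fell, and within the fast genes Casq1 (-2.69) and Mybpc2 (-1.95) fell while Atp2a1 (0.23) rose.

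A weaker induction of PPAR-responsive genes after Plin2 knockdown was also tested as a hypothesis. The median difference of response (Plin2 siRNA minus scrambled) was 0.079 with oleate and 0.20 with palmitate, where a weaker induction needs values below 0. These values leave the hypothesis open, because the list was barely induced in scrambled cells (median 0.08 with oleate, 95% bootstrap interval 0.0013 to 0.17, and -0.04 with palmitate, interval -0.19 to 0.04). Genes that were induced went both ways with palmitate, from scrambled to Plin2 siRNA cells: Angptl4 from 2.02 to 2.36 and Cpt1a from 1.23 to 1.13.

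Of the 12146 unnamed probe sets, 0 were called for Plin2 siRNA in a limma fit of their own, with 1397 at an unadjusted p under 0.05, and 423 were called when all probe sets were fitted together. Their median of mean expression was 3.92, against 5.80 for named probe sets.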
